A study of Mus musculus with 9 samples.

How the data were processed

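Gene expression was measured in 9 samples of mouse RNA, 5 hepatocellular carcinomas of TKO mice and 4 normal livers, on Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols, RNA was extracted with Trizol and amplified in 2 rounds with a RiboAmp kit before hybridisation. The values deposited by the authors are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA as commonly run corrects background, normalises quantiles between arrays and summarises the probes of a probe set. The version of RMA and its settings are not given in the sources used here. The deposited table holds 45101 probe sets on 9 arrays with values from 3.13 to 15.5, and every sample column was used. Amplification from the 3' end can shorten transcripts, and RMA compresses differences of dim probe sets, so a log2 difference near the background understates a change, as can one near the top of the scale. Quantile normalisation gives all arrays nearly 1 distribution, which can hide a general shift in RNA content. Scan batches are not given in the sources used here and no batch was tested.

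Samples were grouped by their titles. Gene names came from the platform annotation that pairs probe sets with symbols: 34945 probe sets named 1 gene, 932 named several and 9160 named none, with 64 controls left out. Symbols were checked through gene identifiers in the RefSeq table of the GRCm38.p6 assembly, where 34741 were found and 0 symbols changed. That table was used only for names and for the order of genes along chromosomes. Probe sets naming several genes or none were not used for genes. For each gene the probe set with the highest mean over all 9 arrays was taken, without regard to group, which gave 18193 genes; 9010 of these had at least 2 probe sets and 1532 were read by probe sets ending in x_at or s_at, which can cross-hybridise with similar genes. For 127 genes, probe sets of the same gene passed in both directions. Of 113 named genes and markers with another probe set above the TrpnX control, 32 had one that differed in call or direction. No filter on dim probe sets was applied in the main setting.

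Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Every sentence with an adjusted p of a gene refers to this test. The 34 tested gene lists were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list and limma's fry were alternatives. With an estimated correlation 3 lists passed: replication, mitosis and homologous recombination. Sex markers and housekeeping genes were listed without a test. Counts of members were also adjusted over the list alone. RNA quality was compared by an exact permutation test over the 126 splits of 9 arrays into 5 and 4, whose smallest two-sided p is 0.00794. Other values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

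The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 3 targeted genes; the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap; up to 4 members of each list, 3 with the smallest adjusted p in the direction most members took and 1 the other way; and the members of the RB and Notch lists with the sex markers. The text draws its examples from these genes. Provisional symbols were counted, 398 among the genes past the threshold, and not named. Alb, Hnf4a, Afp, Krt19 and Epcam are widely used markers outside that rule and were added after their values were seen. The Xist level as a covariate and the removal of the 3 arrays with low Xist were alternatives added after the data had been seen, the latter also with an estimated correlation.

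The gene test was tested on simulated data for the 18193 genes of this comparison with the real spread between arrays. It recovered 32.8% of genes changed by 0.5 log2 units, 67.2% of those changed by 1 and 92.4% of those changed by 2, with 7 other genes called. These changes were planted in 67, 67 and 66 genes, a far smaller share than the 33.5% that passed in the data. Benjamini-Hochberg adjustment is stricter where fewer genes change, so the recovery in the real comparison was not measured. The list test called the list that had been shifted and 0 of 33 others. The chromosome test, run on 11531 simulated genes, recovered a shift of 0.389 where 0.4 had been planted and passed no other pair of tumour and chromosome. Each simulated gene varied independently. These runs therefore do not show how the list and chromosome tests behave where genes vary together. The closest pair of arrays differed by 0.311 log2 units (root mean square), so no array was taken for a duplicate of another. Alternatives were the mean of all probe sets of a gene, no probe sets ending in x_at, s_at or a_at, every probe set on its own, genes above the median level alone, 4 other scalings (housekeeping genes, the 75th percentile, cyclic loess and quantiles), trend and robust variance, array weights, a variance for each group, the replicate number as a block, stricter thresholds and leaving out each array in turn.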

Results

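The study compared hepatocellular carcinomas from a genetically modified mouse with normal mouse liver. The tumours came from mice that the titles call triple knockout (TKO), although the listed genotype gives deletion of both copies of Rb and p130 with 1 intact copy of p107. Rb (gene symbol Rb1), p130 (Rbl2) and p107 (Rbl1) form the retinoblastoma family, whose proteins bind E2F transcription factors and hold back entry into S phase. Per the labels, these mice had received adenovirus carrying Cre recombinase by injection into the spleen 4 months before the tumours were dissected. The control livers were wild-type, adult and free of tumours, so genotype, virus and tumour state differed together between the groups. RNA from 5 tumours and 4 livers was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, and 18193 genes were compared on the log2 scale. The median over all probe sets lay between 6.22 and 6.27 on every array, and the number of arrays limits the precision. No label states in so many words that the samples of a group came from separate animals, so the p-values measure the spread between these samples.

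The arrays fell into the groups that the labels gave. Across all genes, Pearson's r was 0.958 to 0.981 between tumours, 0.978 to 0.991 between livers and 0.905 to 0.938 between a tumour and a liver (correlations across genes, which are not independent replicates). On the axis from the mean liver at 0 to the mean tumour at 1, each array placed without its own values, the tumours stood at 1.06, 0.75, 1.05, 0.84 and 1.02 and the livers between -0.01 and 0.10. The median SD of a gene was 0.190 among tumours and 0.162 among livers, and 58.0% of genes had the larger SD among tumours. The log2 ratio of the 3' to the 5' probe sets of the Actb control, a measure of RNA length, was 0.61 ± 0.08 (SD, n = 5) in tumours and 0.96 ± 0.04 (SD, n = 4) in livers, and all tumours lay below all livers (exact permutation test, two-sided p = 0.00794, the smallest this design allows, and 0.0159 after Benjamini-Hochberg adjustment over 2 controls). For the Gapdh control the ratio was -0.21 ± 0.03 (SD, n = 5) and -0.28 ± 0.05 (SD, n = 4), with an exact two-sided p of 0.0635. This RNA measure ran with the tumour and liver groups in every gene group described here. Sex is not given in the sources used here, and both groups held arrays of low and of high Xist. Xist, the RNA that silences 1 X chromosome in females, was 6.34 and 6.39 in tumours 1 and 2 and 6.66 in liver 4, against 12.68 to 13.55 in the other 6 arrays, and the Y-linked gene Eif2s3y was 9.16 to 10.3 in those 3 arrays and 3.55 to 4.32 elsewhere.

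Of the targeted genes, Rbl2 was lower in the tumours, Rb1 was higher and Rbl1 lay near background in both groups. Rbl2 fell from 9.80 ± 0.25 (SD, n = 4) in livers to 7.81 ± 0.64 (SD, n = 5) in tumours, a log2 difference of -1.99 (SE 0.30, limma adjusted p = 0.00126). Its tumour values were 6.77, 8.43, 7.72, 7.98 and 8.16 and its liver values 10.02, 9.90, 9.44 and 9.84, and its other probe set differed by -1.91. Rb1 rose by 1.05 (SE 0.17, adjusted p = 0.0018), with tumour values of 8.77, 9.21, 9.04, 8.76 and 9.38 and liver values of 8.33, 7.69, 7.85 and 8.06. A second Rb1 probe set averaged 4.41 in tumours and 4.33 in livers. Rbl1 was 4.81, 4.81, 4.74, 4.82 and 4.63 in tumours and 4.74, 4.97, 5.83 and 4.23 in livers, a log2 difference of -0.18 (95% interval -0.78 to 0.42, adjusted p = 0.619) that was 0.014 after centring on housekeeping genes and 0.12 without liver 3, and the bacterial TrpnX control, which has no target in mouse RNA, read 3.69 to 4.36. The deleted exons are not given in the sources used here, and a probe set outside the deleted part checks nothing about the genotype.

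The question the comparison addresses is how gene expression in these tumours differed from that of normal liver. Among the tested gene lists, mitosis genes had the highest median log2 difference, 4.06, and genes of hepatocytes around the central vein the lowest, -3.25. Tff3, a secreted trefoil peptide of mucosal surfaces, averaged 14.12 ± 0.36 (SD, n = 5) in tumours and 6.69 ± 0.11 (SD, n = 4) in livers, a 172-fold difference (log2 7.43, SE 0.18). Birc5, which encodes the mitotic regulator survivin, rose by 6.89 (SE 0.19) and Ccnb2, a mitotic cyclin, by 6.42 (SE 0.16). Nnmt, which methylates nicotinamide, fell by 6.68 (SE 0.36) on the log2 scale, and Cyp2c50, a cytochrome P450 of central-vein hepatocytes, by 6.40 (SE 0.62).

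In all, 6091 of the 18193 genes (33.5%) passed an adjusted p of 0.05 with limma, 2926 higher and 3165 lower in the tumours. At 2-fold or more there were 1187 higher and 796 lower, and at 8-fold or more 182 higher and 84 lower. The 48% share of higher calls depended on scaling: it was 77.6% (2765 higher, 796 lower) with arrays centred on housekeeping genes and 22.6% (2328 higher, 7982 lower) with arrays centred on their 75th percentile. These settings moved the median log2 difference of all genes from -0.08 to 0.11 and to -0.26, respectively. After centring on housekeeping genes some named changes no longer passed, with SEs of 0.20 to 0.25 against 0.07 to 0.18 before. These were Fas (-0.70), Sp5 (-0.68), Apob (-0.42), Asb4 (-0.39), Hnf4g (-0.37), Blk (-0.30), Stmn2 (-0.15), Hey2 (-0.11) and Insm1 (-0.10), and Ahsg (0.59) and Cux2 (0.66), whose increases were larger than without it. Dimmer probe sets, with group means of 4.12 to 6.05, did not pass for Top2a (-0.25), Chek1 (-0.34), Psrc1 (0.38), E2f1 (0.046), Gata6 (-0.0044), Acacb (-0.18), Asb4 (-0.17), Axin2 (-0.066), Hsd17b13 (-0.039), Pdk1 (-0.26), Reln (-0.092) and Tbx3 (-0.24), whose other values given here come from brighter ones. Of 14 measured housekeeping genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.51. The level used for centring, each array's median over these genes, was 12.17 to 13.00 in tumours and 12.73 to 12.98 in livers. That level varied between tumours and was not raised in them as the members' differences were, which limits this scaling. The 5 tumour values and 4 liver values did not overlap for 5430 genes, 4948 of them past the threshold, and chance gives 1.59% of genes. Among the 12 largest increases were also Esco2 at 6.82, D17H6S56E-5 at 6.54, Pbk at 6.53, Pclaf at 6.36, Top2a at 6.36, Uhrf1 at 6.29, Rrm2 at 6.24, Mcm6 at 6.02 and Psrc1 at 5.85. Esco2 joins sister chromatids, Top2a untangles DNA, Uhrf1 maintains DNA methylation and Rrm2 makes deoxyribonucleotides. Pbk and Rrm2 were read by probe sets that can cross-hybridise with similar genes. The 12 largest decreases also held Sult3a1 at -6.33, Cyp2c37 at -5.82, Oat at -5.75, Cyp2c54 at -5.74, Lect2 at -5.51, Hamp at -5.46, Cyp7a1 at -5.39, Cyp1a2 at -5.34, Slc1a2 at -5.26 and Agxt at -4.97. Cyp7a1 is the rate-limiting enzyme of bile acid synthesis and Hamp encodes the iron hormone hepcidin, and in tumour 2 these stood at 11.20 and 14.43, close to the liver means of 12.53 and 14.68. Sult3a1 was 4.43 in liver 4, near the tumour mean of 3.89, and 11.09 to 12.80 in the other 3 livers. The liver mean of Esco2, 3.70, and the tumour mean of Sult3a1 lay in the range of the TrpnX control, so the full size and rank of these differences were not measurable.

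**Figure D1:**
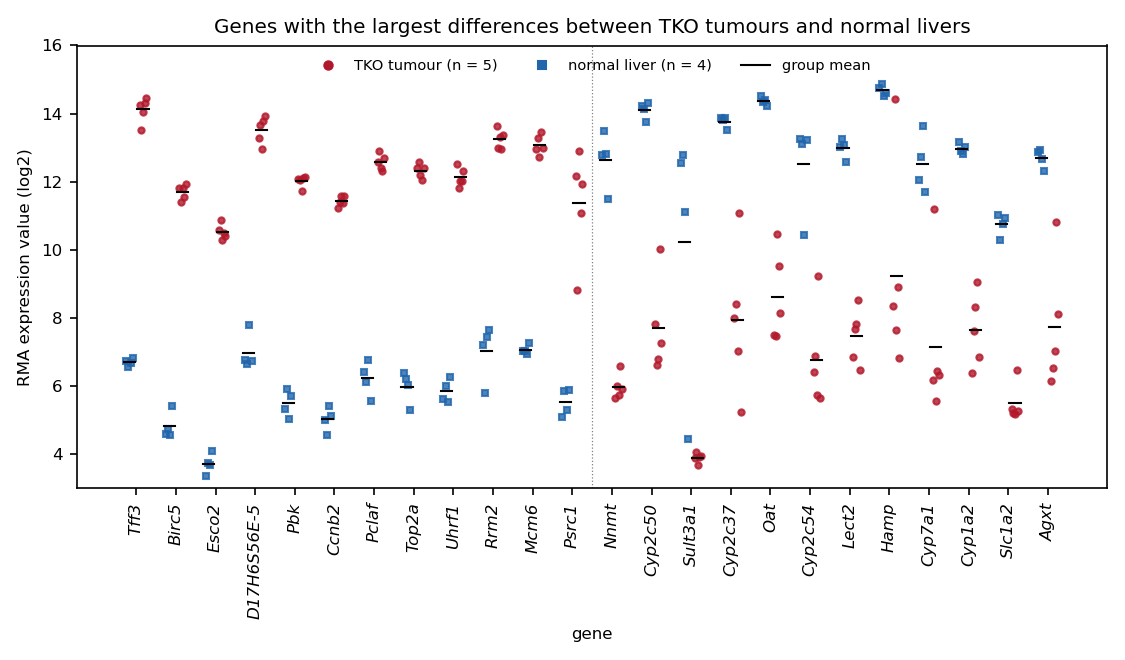
Log2 expression (vertical axis, log2 units) of the 12 genes with the largest increase and the 12 with the largest decrease (horizontal axis), 1 point per array for 5 TKO tumours and 4 normal livers, with a bar at each group mean. Tff3 averaged 14.12 in tumours and 6.69 in livers, while tumour 2 kept Hamp at 14.43 and liver 4 held Sult3a1 at 4.43.

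The replication and mitosis genes rose nearly as complete sets. Of 46 measured DNA replication and G1/S genes, 43 rose and 1 fell (44 and 1 adjusted over the list alone), with a median log2 difference of 2.82 and an adjusted p of 1.9e-38 against all other genes (0.0106 with an estimated correlation). Mcm6, a subunit of the replicative helicase, rose 65.1-fold, Cdc6, which loads that helicase, rose by 5.64 (SE 0.15), and Mcm7, read by a probe set open to cross-hybridisation, rose by 4.19 (SE 0.12). Mcm10 fell by 1.27 with the probe set used, but another of its probe sets rose by 0.80 and the mean of its probe sets gave -0.21. Of 47 mitosis genes, 46 rose and none fell (46 and 0 adjusted over the list alone), with a median of 4.06 and an adjusted p of 3.5e-47 (0.0158 with an estimated correlation). Racgap1, needed for cytokinesis, rose by 5.19 (SE 0.14), and Birc5 and Ccnb2 belonged to this list. Homologous recombination and DNA damage response genes followed, with 22 of 27 up and none down (22 and 0 adjusted over the list alone), a median of 2.26 and an adjusted p of 1.8e-17 (0.0278 with an estimated correlation). They included the nuclease gene Exo1 at 2.91 (SE 0.10), the checkpoint gene Topbp1 at 3.00 (SE 0.14) and the checkpoint kinase gene Chek1 at 5.11 (SE 0.15), the last from a cross-hybridising probe set.

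Regulators around the retinoblastoma family moved both ways. Of 31 genes in the RB family, E2F and CDK list, 18 rose and 3 fell (20 and 4 adjusted over the list alone), with a median of 1.05 and an adjusted p of 9.9e-07 (0.0592 with an estimated correlation). The list counts the 3 targeted genes: Rbl2 was 1 of those that fell, and the median was the value of Rb1. The activator E2f1 rose by 2.26 (SE 0.13) and the atypical repressors E2f7 and E2f8 by 3.48 (SE 0.27) and 3.16 (SE 0.25), whereas E2f3 differed by -0.02 (95% interval -0.33 to 0.30) and E2f2 by 0.44 without passing, while another probe set of E2f2 passed at 1.27. Lin9 and Lin54 of the MuvB complex, which controls cell-cycle genes, rose by 2.29 and 1.68. Of the listed genes for inhibitors of cyclin-dependent kinases, Cdkn1c differed by 0.47 (SE 0.56, adjusted p = 0.536). Cdkn1a (p21) rose by 4.88 (SE 0.44), Cdkn2d by 2.87 (SE 0.24), Cdkn1b (p27) by 2.24 (SE 0.32), Cdkn2c by 2.16 (SE 0.25), Cdkn2b by 1.75 (SE 0.51) and Cdkn2a by 1.08 (SE 0.25), the last from a liver mean of 4.33 in the range of the TrpnX control. The call of Cdkn2b was lost without tumour 1 (1.51) or any of livers 1 to 4 (1.69, 1.76, 1.78 and 1.77). The G1 gene Ccnd1 fell by 2.56 (SE 0.38). Cdk6, another G1 gene, fell by 2.13 (SE 0.21), whereas Cdk4, read by a cross-hybridising probe set, rose by 1.45 (SE 0.12). Ccnd2 and Ccnd3 differed by -0.47 (SE 0.16) and 0.40 (SE 0.15) without passing, while 3 other probe sets of Ccnd2 passed at -0.63, -0.59 and -0.49. Cdk2 rose by 2.31 with the probe set used, while its other probe set, near background at 3.46 and 3.63, gave -0.16. The p53 targets held 9 that rose and 3 that fell among 22 (11 and 3 adjusted over the list alone), with a median of 0.71 and an adjusted p of 0.0136 (0.563 with an estimated correlation). Besides Cdkn1a, the apoptosome gene Apaf1 rose by 1.48 (SE 0.31) and Phlda3 by 2.26 (SE 0.49), while the death receptor gene Fas fell by 0.89 (SE 0.18).

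The Notch pathway list was chosen with knowledge that the study had examined Notch signalling, so it is not independent evidence of a direction. Of 40 genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), the median was 0.09, -0.09 with arrays centred on the 75th percentile, and the list did not pass against all other genes (adjusted p = 0.0825, or 0.361 with an estimated correlation). The fry test, which asks whether the members moved one way on balance, gave an adjusted p of 0.00563. Notch1, a receptor, rose by 1.65 (SE 0.20), the feedback inhibitor Nrarp by 2.06 (SE 0.36), Dtx4 by 1.33 (SE 0.19; 0.53 and not past with its other probe set) and Hes1, a classical Notch target, by 1.24 (SE 0.29). Hey2 fell by 0.31 at means of 3.76 in tumours and 4.06 in livers, which is in the range of the TrpnX control, and its call was lost without tumour 1 (-0.29), tumour 3 (-0.29), tumour 4 (-0.31), tumour 5 (-0.31), liver 1 (-0.28), liver 3 (-0.24) or the 3 arrays with low Xist (-0.37). The other members that rose were Notch4, Dll1, Sox9, Snw1 and Ncstn. Without the 3 arrays with low Xist the calls of Hes1 (1.19), Notch4 (0.97) and Dll1 (0.54) were lost. Sox9 and Snw1 lost theirs in several settings, among them without tumour 1 (1.20 and 0.31) or liver 1 (1.28 and 0.33). Notch4 also lost its call without liver 1 (0.96), liver 2 (0.99) or liver 4 (0.96). Other probe sets did not pass for Notch4 (-0.19), Sox9 (0.86 and 0.06), Snw1 (-0.18) and Ncstn (0.05). The receptor gene Notch2 differed by 0.42 (adjusted p = 0.0952), the ligand gene Jag1 by 0.04 (SE 0.43) and the DNA-binding partner Rbpj by -0.29 (adjusted p = 0.0973).

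Metabolic genes of mature hepatocytes fell in several lists, each of which passed against other genes but not with an estimated correlation. Cytochrome P450 and drug metabolism genes had 24 of 42 down and none up (25 and 1 adjusted over the list alone), with a median of -1.20 and an adjusted p of 4e-05 (adjusted p = 0.116 with an estimated correlation). Cyp1a2 fell by 5.34 (SE 0.48) and Cyp2c23, read by a cross-hybridising probe set, by 3.52 (SE 0.33). Of 37 urea cycle and amino acid breakdown genes, 16 fell and none rose (17 and 0 adjusted over the list alone), with a median of -0.94 and an adjusted p of 7.8e-05 (adjusted p = 0.576 with an estimated correlation). Glul, the glutamine synthetase gene, fell by 3.08 (SE 0.30), Oat, the ornithine aminotransferase gene, by 5.75 (SE 0.59) and Got1 by 2.95 (SE 0.30). Fatty acid oxidation and ketone body genes had 15 of 31 down and none up (17 and 0 adjusted over the list alone), with a median of -0.68 and an adjusted p of 7.8e-05 (adjusted p = 0.481 with an estimated correlation), and Decr1 and the carnitine carrier gene Slc25a20 fell by 1.36 (SE 0.12) and 1.29 (SE 0.13). In the bile acid list 13 of 30 fell and 1 rose (16 and 3 adjusted over the list alone), with a median of -1.20 and an adjusted p of 0.00219 (adjusted p = 0.425 with an estimated correlation). Cyp8b1, which sets the share of cholic acid, fell by 4.68 (SE 0.33) and Slc27a5 by 2.91 (SE 0.36), while Slc51b, a subunit of a bile acid exporter, rose by 1.58 (SE 0.41).

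Gluconeogenesis and glycogen genes had 6 of 17 down and none up (6 and 0 adjusted over the list alone), with a median of -0.68 and an adjusted p of 0.0407 (adjusted p = 0.424 with an estimated correlation), and the call was lost without liver 1 (-0.67) or liver 4 (-0.56). Slc37a4, the glucose 6-phosphate carrier gene, fell by 1.35 (SE 0.22) and Fbp1 by 1.65 (SE 0.35). Among 44 hepatocyte secreted proteins, 14 fell and 3 rose (14 and 3 adjusted over the list alone), with a median of -0.24 and an adjusted p of 0.0407 (adjusted p = 0.748 with an estimated correlation). That call was lost without tumour 1 (-0.21), tumour 3 (-0.17), liver 1 (-0.23) or liver 2 (-0.21). Apoc4 fell by 1.76 (SE 0.22), Itih1 fell 2.83-fold (SE 0.18 on the log2 scale) and Apob by 0.61 (SE 0.09), Ahsg rose by 0.40 (SE 0.09), and Alb, the albumin gene, differed by 0.085 (SE 0.08). Ahsg and Alb lay close to the highest deposited value, where differences can be compressed. The cholesterol and fatty acid synthesis list did not pass (median -0.43, adjusted p = 0.22), with 9 of 32 down and 3 up (9 and 3 adjusted over the list alone). Acacb fell by 2.56 (SE 0.38). Elovl6 fell by 2.13 (SE 0.43; -0.61 and not past with another probe set), whereas Scd2, a stearoyl-CoA desaturase little expressed in adult liver, rose by 4.99 (SE 0.46). Nor did glycolysis and hypoxia genes pass (median 0.07, adjusted p = 0.0907), with 7 of 29 up and 3 down (7 and 3 adjusted over the list alone). The list's median was -0.01 without tumour 3. The list passed with every probe set on its own (0.14), without the 3 arrays with low Xist (0.28) and with arrays centred on the 75th percentile (-0.11). In that last setting all genes had a median of -0.26, so the list lay above them. The phosphofructokinase genes Pfkl and Pfkp rose by 1.61 (SE 0.17, or 0.64 and not past with another probe set) and 2.95 (SE 0.32). Pdk1, a pyruvate dehydrogenase kinase gene, fell by 3.85 (SE 0.55). Hepatocyte transcription factors had 3 of 24 up and 2 down (3 and 2 adjusted over the list alone), with a median of 0.18, -0.04 without tumour 2, a mean of -0.05, a test direction of up and an adjusted p of 0.514. Gata6 rose by 1.46 (SE 0.12) and Hnf4g fell by 0.57 (SE 0.07), and Hnf4a, a central hepatocyte factor, differed by 0.20 (SE 0.17).

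Genes of the pericentral zone, the hepatocytes around the central vein, fell most among the liver lists. Of 26 measured, 20 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -3.25 and an adjusted p of 4e-08 (adjusted p = 0.152 with an estimated correlation). Slc1a2, a glutamate transporter gene, fell by 5.26 (SE 0.28), and Lect2 by 5.51 (SE 0.38). The transcription factor gene Tbx3 fell by 3.23 (SE 0.19), while Gstm3, read by a cross-hybridising probe set, rose by 2.44 (SE 0.45). Periportal genes, those around the portal vein, had 8 of 27 down and 2 up (8 and 3 adjusted over the list alone), with a median of -0.51 and an adjusted p of 0.0807. That list passed without tumour 2 (-0.62), tumour 4 (-0.64) or tumour 5 (-0.51), and its median was nearest 0 without tumour 1 (-0.36). Mfsd2a, a lipid transporter gene, fell by 4.13 (SE 0.44). Igf1 fell by 3.22 (SE 0.37), and Hsd17b13, a lipid droplet protein gene, rose by 1.31 (SE 0.13). Wnt targets, which share Axin2, Lgr5 and Tbx3 with the pericentral list, had 6 of 17 down and 2 up (6 and 2 adjusted over the list alone), with a median of -0.23 and an adjusted p of 0.0403 (adjusted p = 0.424 with an estimated correlation), a call lost without tumour 2 (-0.23) or liver 1 (-0.21). Axin2, a general target of beta-catenin, fell by 0.93 (SE 0.12) and Sp5 by 0.87 (SE 0.09), and Myc rose by 0.87 (SE 0.17).

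**Figure D2:**
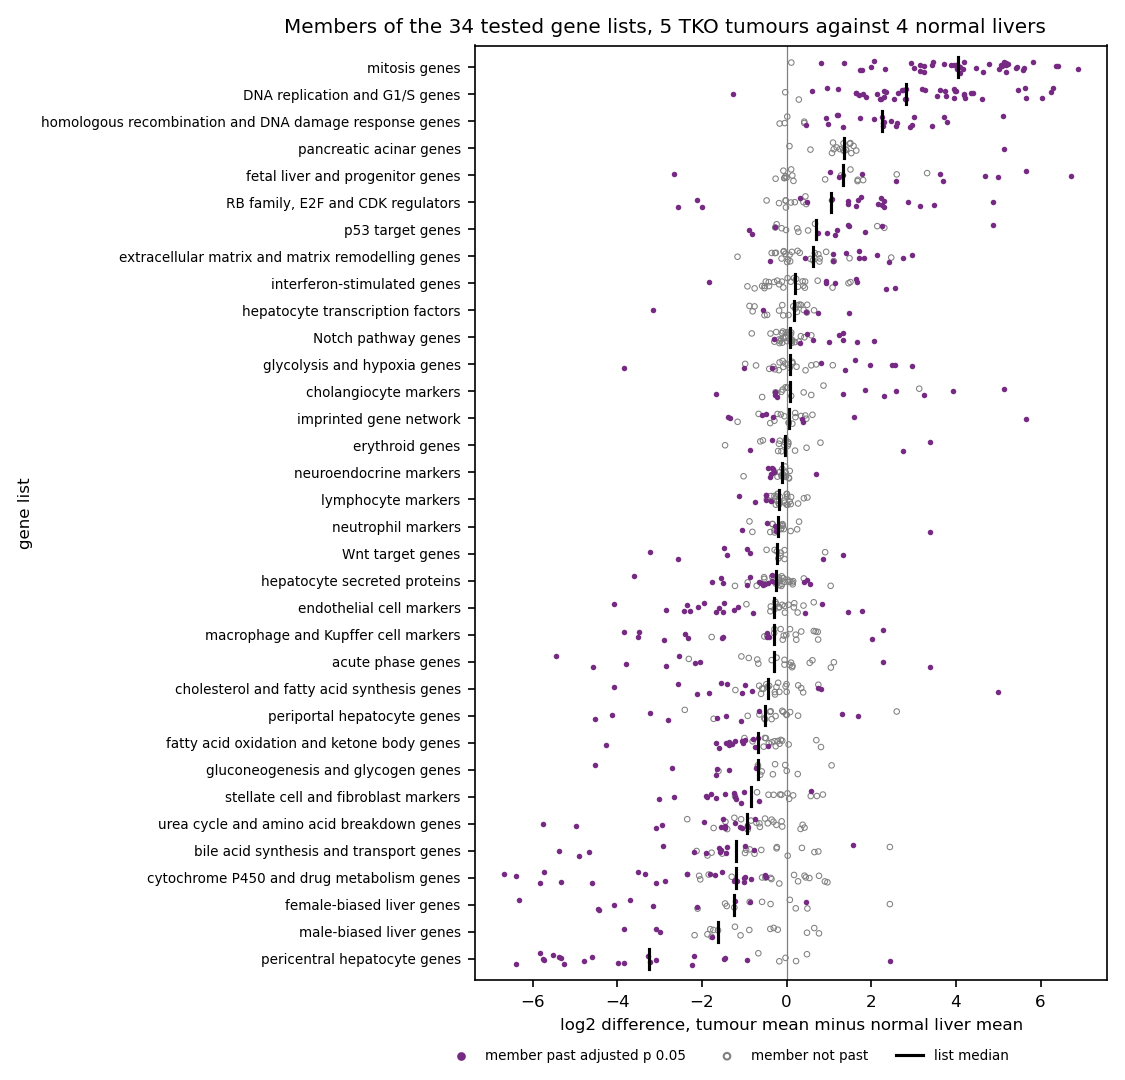
Log2 difference between the tumour mean and the normal liver mean (horizontal axis, log2 units) for each measured member of the 34 tested gene lists (vertical axis), filled where the member passed an adjusted p of 0.05, with a bar at each list median. Mitosis genes had a median of 4.06 and pericentral genes one of -3.25, while the medians of the Notch, glycolysis, imprinted, cholangiocyte, neuroendocrine, lymphocyte and erythroid lists lay between -0.18 and 0.09 and changed sign under another scaling of the arrays.

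Fetal liver and progenitor genes were higher in the tumours. Of 29 measured, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 1.32 and an adjusted p of 1.9e-04 (adjusted p = 0.424 with an estimated correlation). Golm1, a Golgi protein gene raised in liver disease, rose by 3.70 (SE 0.23) and Vil1, which encodes the microvillus protein villin, by 4.69 (SE 0.62), while Reln fell by 2.66 (SE 0.36). Afp, the alpha-fetoprotein gene, differed by 1.81 (SE 0.92) without passing. Igf2, a fetal growth factor gene, was 14.03 to 15.09 in 4 tumours, 6.87 in tumour 4 and 7.33 to 7.62 in livers, a log2 difference of 5.66 (SE 1.56, adjusted p = 0.0215) whose call was lost without tumour 5 (5.23), liver 1 (5.63), liver 2 (5.62) or the 3 arrays with low Xist (4.48). The imprinted gene network as a whole had 4 of 25 up and 5 down (4 and 5 adjusted over the list alone), with a median of 0.05, a mean of 0.14, a test direction of down and an adjusted p of 0.904, and its median was -0.13 with arrays centred on the 75th percentile. It was also below 0 without tumour 3 (-0.03), tumour 5 (-0.05) or liver 4 (-0.03). Besides Igf2 it held Slc38a4, an amino acid transporter gene that fell by 1.38 (SE 0.32), and Asb4, which fell by 0.58 (SE 0.12), or -0.53 and not past without the 3 arrays with low Xist. Its tumour mean of 4.23 lay in the range of the TrpnX control, so the full size was not measurable. Cholangiocyte markers had 7 of 24 up and 4 down (7 and 4 adjusted over the list alone), with a median of 0.07 that was -0.11 with arrays centred on the 75th percentile, an adjusted p of 0.0825 and a call gained without tumour 2 (0.04). The tight junction gene Cldn7 rose by 5.14 (SE 0.26), Wfdc2 by 3.94 (SE 0.45) and the epithelial factor gene Elf3 by 1.85 (SE 0.25), whereas the bile duct keratin gene Krt19 differed by -0.26 (SE 0.16) and Epcam by 0.11 (SE 0.08). Neuroendocrine markers had 1 of 23 up and 6 down (1 and 6 adjusted over the list alone), with a median of -0.11 that was 0.08 after centring on housekeeping genes and an adjusted p of 0.139. Rest, the repressor of neuronal genes, rose by 0.70 (SE 0.09), but its other probe sets gave 0.20, -0.24 and -0.03 without passing, and Stmn2 and Insm1 fell by 0.35 (SE 0.08) and 0.30 (SE 0.07). With the mean of their probe sets Stmn2 (-0.25) and Insm1 (-0.16) did not pass either, and the tumour mean of Insm1, 4.34, lay in the range of the TrpnX control.

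Markers of the liver's other resident cells were lower in part. Stellate cell and fibroblast markers had 13 of 26 down and 1 up (13 and 1 adjusted over the list alone), with a median of -0.85 and an adjusted p of 0.00587 (adjusted p = 0.543 with an estimated correlation). Ecm1 fell by 3.01 (SE 0.24) and Vipr1 by 1.67 (SE 0.18), and the contractile gene Tagln rose by 0.57 (SE 0.16), a call lost without liver 1 (0.51), liver 4 (0.49) or the 3 arrays with low Xist (0.54). Endothelial markers had 14 of 35 down and 4 up (14 and 5 adjusted over the list alone), with a median of -0.29 and an adjusted p of 0.0407 (adjusted p = 0.74 with an estimated correlation). That call was lost without tumour 1 (-0.16), tumour 5 (-0.32), liver 1 (-0.27), liver 2 (-0.23) or liver 3 (-0.22). Bmp2, an angiocrine factor gene, fell by 2.86 (SE 0.30), the sinusoidal nuclease gene Dnase1l3 by 2.29 (SE 0.29) and the receptor gene Kdr by 1.15 (SE 0.12), whereas Cd34, which marks capillary rather than sinusoidal endothelium, rose by 1.77 (SE 0.28). Macrophage and Kupffer cell markers had 11 of 30 down and 2 up (11 and 2 adjusted over the list alone), with a median of -0.29 and an adjusted p of 0.105, and the list passed without tumour 3 (-0.43) or liver 4 (-0.40), while the median was -0.16 without tumour 1 and -0.13 without tumour 2. The Kupffer cell genes Clec4f and Timd4 fell by 3.51 (SE 0.57) and 2.90 (SE 0.19), and Cd14 rose by 2.28 (SE 0.41). Extracellular matrix and remodelling genes moved the other way, with 11 of 37 up and 1 down (11 and 1 adjusted over the list alone), a median of 0.62 and an adjusted p of 0.00109 (adjusted p = 0.62 with an estimated correlation), and the median was 0.37 without tumour 3. The basement membrane genes Col4a1 and Nid1 rose by 2.75 (SE 0.35) and 2.42 (SE 0.29) and the collagenase gene Mmp13 by 2.97 (SE 0.32).

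Blood cell and inflammation lists did not pass. Lymphocyte markers had 6 of 32 down and none up, but 1 down and 0 up adjusted over the list alone, with a median of -0.18 that was 0.01 after centring on housekeeping genes and an adjusted p of 0.249. Blk, a B cell kinase gene, fell by 0.49 (SE 0.10) at means of 5.50 and 5.99. Neutrophil markers had 4 of 22 down and 1 up (2 and 0 adjusted over the list alone), with a median of -0.20 and an adjusted p of 0.199, and Il1b fell by 1.06 (SE 0.22). Erythroid genes had 2 of 20 up and 2 down (2 and 2 adjusted over the list alone), with a median of -0.05 that was 0.15 after centring on housekeeping genes, a mean of 0.15, a test direction of down and an adjusted p of 0.904. The carbonic anhydrase gene Car2 rose by 3.38 (SE 0.40) and the transferrin receptor gene Tfrc by 2.75 (SE 0.45). Acute phase genes had 7 of 26 down and 2 up (7 and 2 adjusted over the list alone), with a median of -0.30 and an adjusted p of 0.286, and the serum amyloid genes Saa1 and Saa4 fell by 4.58 (SE 0.72) and 2.17 (SE 0.35). Interferon-stimulated genes had 7 of 34 up and 1 down, but 2 up and 0 down adjusted over the list alone, with a median of 0.20 and an adjusted p of 0.122, and the list passed without tumour 2 (0.30), while the median was 0.0054 without tumour 4. Oas1a and Usp18, both induced by interferon, rose by 2.56 (SE 0.42) and 2.34 (SE 0.42).

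Pancreatic and sex-dependent lists differed between single arrays. Pancreatic acinar genes had a median of 1.35 and an adjusted p of 0.0407 (adjusted p = 0.748 with an estimated correlation), with 1 of 18 up and none down (1 and 0 adjusted over the list alone). Their median was -0.11 without tumour 1, the call was also lost without any of livers 1 to 4 (1.37, 1.35, 1.32 and 1.40), and the list median of tumour 1 was 13.4 against 5.76 to 6.08 in the other tumours. The member that rose was the trypsin inhibitor gene Spink1, at 10.77 to 11.79 in the 5 tumours and 5.85 to 6.43 in livers. Male-biased liver genes had 4 of 19 down and none up (3 and 0 adjusted over the list alone), with a median of -1.62 and an adjusted p of 0.0825, and passed without tumour 2 (-1.67), liver 1 (-1.98) or liver 3 (-1.86). Without liver 4 the median was -0.29, and the list did not pass. Egfr, the epidermal growth factor receptor gene, fell by 3.00 (SE 0.56). Female-biased liver genes had 9 of 21 down and 1 up (10 and 2 adjusted over the list alone), with a median of -1.24 and an adjusted p of 0.0907, and passed without liver 4 (-1.92), with a median nearest 0 of -1.00 without liver 1. Slc22a26 fell by 4.44 (SE 1.10), with 6.67 in liver 4 and 11.92 to 12.68 in the other 3 livers. Cux2, a female-biased transcription factor gene, rose by 0.47 with the probe set used, whereas its other probe sets gave -2.98 and -0.73. Of the 4 measured X- and Y-linked sex markers none passed (0 rose and 0 fell, also adjusted over the list alone), with a median of 0.06 and a mean of -0.08.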

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

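Every test of an explanation given here, the count of other splits, the acinar, islet and array-position tests and the setting without 3 arrays, was chosen after the result it bears on had been seen. Of 386 groups of values examined, 29 held an array far from the rest of its group by Dixon's criterion, which chance exceeds in about 1 in 20 groups. At that rate chance may account for most of the 29, so a value listed as standing apart is no evidence by itself. Liver 3 had 6 of these values, tumour 2 had 5, liver 4 had 4 and tumour 5 had 0. The other splits of the arrays bear on the count of 6091 genes. Of the 126 possible splits 100 were run, the real one put in on purpose and the rest drawn at random. Only the real one gave as many. The highest other split gave 3682 genes and put 4 of the tumours together against the livers and the remaining tumour. The next highest gave 2070, and the median was 0. These values argue against a random labelling of the arrays as the source of the count. Mixed splits put any group difference on both sides, so their low counts cannot tell tumour state from other group differences.

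Pancreatic acinar genes stood apart in tumour 1, where their median level was 13.44 against 5.76 to 6.08 in the other tumours. The list was written before the data were examined, as a tissue near the liver, and 5 of its 18 members lie above the median level of all probe sets in each of the other 8 arrays while 0 belong to another list. In tumour 1, 16 of the 18 members were at least 1 log2 unit above all other arrays, by a median of 7.26, with Cela2a at 14.64, Cpa1 at 14.58 and Prss2 at 14.55, while Ptf1a exceeded them by 0.66 and Spink1 did not. A mislabelled sample is argued against, since tumour 1 stood at 1.06 on the axis from liver (0) to tumour (1), and so are islet cells, of whose 6 measured genes 0 exceeded the other arrays by 1 log2 unit. Acinar cells of the pancreas in the dissected piece are a candidate explanation, and an acinar programme in the tumour's own cells stays open and untested, as no sort or gate is named that would remove other cells.

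Female-biased liver genes were lower in the tumours by a median of -1.24 without passing (adjusted p = 0.0907), and liver 4, which like tumours 1 and 2 had low Xist and high Eif2s3y, stood apart for Slc22a26 at 6.67 against 11.92 to 12.68. Without these 3 arrays the list's median was -1.55, and the 3 tumours left had list medians of 7.82 to 8.51 against 9.97 to 10.75 in the 3 livers left, which argues against the mix of sexes as the whole cause in these 6 arrays. The list then passed with the preset correlation (adjusted p = 5.3e-05) but not with an estimated one (0.145), against a range of 2.8e-05 to 0.748 over all alternatives, whose upper end is all 9 arrays with an estimated correlation. Male-biased genes also stood apart, with list medians of 12.93 in liver 4 against 7.42 to 7.52 in the other livers and 8.88 in tumour 2 against 6.92 to 7.12 in the other tumours. Among the 3 arrays with low Xist the order was turned, with female-biased list medians of 7.92 and 8.13 in tumours 1 and 2 against 6.34 in liver 4, the only such liver, so whether the difference between tumour and liver depends on sex stays open and untested.

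Tumour 2 stood apart for 4 genes. Hamp was 14.43 there and 6.82 to 8.90 in the other tumours, Cyp7a1 11.20 against 5.56 to 6.44, Lin54 9.94 against 9.42 to 9.56 and Elf3 8.31 against 9.09 to 9.27. In tumour 4, Igf2 was 6.87 against 14.03 to 15.09, Slc1a2 6.45 against 5.17 to 5.32 and Nrarp 8.34 against 9.48 to 9.69. In tumour 3, Mmp13 was 8.89 against 7.16 to 7.54, Pbk 11.74 against 12.06 to 12.14 and Ctsg 5.42 against 5.71 to 5.82. Acute phase genes had a median of 9.62 in tumour 1 against 10.74 to 10.96 in the other tumours.

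Among livers, values in liver 3 were Cyp2c54 at 10.44 against 13.11 to 13.26, Hsd17b7 at 12.13 against 10.94 to 11.03 and D17H6S56E-5 at 7.78 against 6.63 to 6.76. Liver 3 also held Exo1 at 5.11 against 5.38 to 5.43, Apoc4 at 13.91 against 14.18 to 14.21 and cholesterol and fatty acid synthesis genes with a median of 11.99 against 10.88 to 11.04. Liver 1 held Vipr1 at 8.40 against 7.80 to 7.88, Reln at 11.08 against 10.96 in the others and p53 targets with a median of 8.05 against 8.27 to 8.31. Liver 2 held Hsd3b7 at 13.25 against 12.86 to 12.93, Aqp1 at 10.94 against 11.09 to 11.11 and Lin54 at 8.01 against 7.82 to 7.84. Liver 4 held Cdk4 at 9.01 against 9.11 to 9.13 and macrophage and Kupffer cell markers with a median of 8.38 against 9.08 to 9.15.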

How the results depend on the processing

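Most values of named genes and lists kept their direction and side of the threshold: 3405 of the gene values across settings, with 210 losing the call and 5 reversed, and 721 of the list values, with 55 losing a call, 54 gaining one and 21 reversed. Nearly all these genes had been taken because they passed in the main setting, so a gained call was hardly possible. Settings that change only the variance cannot reverse a gene. The gene counts therefore do not describe genes in general. The replication, mitosis and homologous recombination lists passed in every setting run but 1: without the 3 arrays with low Xist and with an estimated correlation, 0 of 34 lists passed. The Xist settings were added after the data had been seen. Where a direction reversed, the cause was not tested unless stated. Of the counts of higher and lower genes under other settings, 41 were within 1.5 times of 2926 and 3165, 3 were larger and 6 smaller. Those outside were every probe set on its own (6093 and 6579, more features tested), centring on housekeeping genes (796 lower), centring on the 75th percentile (7982 lower), the replicate block (1531 lower), 2-fold or more (1187 and 796) and an adjusted p under 0.01 (1879 and 1425). The replicate number as a block, without tumour 5, also gave imprinted -0.046 (reversed), endothelial -0.32 (lost), and gained calls for periportal -0.51, neutrophil -0.31 and male-biased -1.51. The same-numbered tumour and liver correlated at -0.129, -0.0668, 0.180 and -0.121, and 1 of 4 tumours correlated best with its own number. These values gave no sign that the numbers pair the samples, but so few pairs cannot exclude it. With an estimated correlation, calls at unchanged medians were lost for RB, E2F and CDK 1.05, p53 0.71, secreted -0.24, urea cycle -0.94, gluconeogenesis -0.68, bile acid -1.20, P450 -1.20, fatty acid oxidation -0.68, fetal 1.32, Wnt -0.23, pericentral -3.25, endothelial -0.29, stellate -0.85, matrix 0.62 and acinar 1.35. With fry, which does not compare with other genes, calls were lost for secreted -0.24, matrix 0.62 and acinar 1.35. It gained Notch 0.091, periportal -0.51, cholangiocyte 0.068 and neuroendocrine -0.11. A variance for each group lost secreted -0.24, gluconeogenesis -0.68, Wnt -0.23 and endothelial -0.29, and among named genes Hamp, Sult3a1, Slc22a26, Igf2, Mcm10, Fas, Hey2, Cdkn2b and Tagln. The mean of probe sets gained Notch 0.12 and female-biased -1.23, lost endothelial -0.24 and reversed Cux2 (-1.08, past the other way), whose probe sets disagree. Without probe sets ending in x_at, s_at or a_at, Notch 0.11, cholangiocyte 0.58 and male-biased -1.73 passed, and imprinted -0.14, Mcm10 0.80 (past the other way) and Cdk2 -0.16 reversed, for the genes because another probe set was read. Every probe set on its own gained Notch 0.11, cholesterol -0.31, glycolysis 0.14, periportal -0.51, cholangiocyte 0.30, neuroendocrine -0.16, macrophage -0.25, male-biased -1.35 and female-biased -0.91. It lost secreted -0.19 and reversed imprinted -0.051. Genes above the median level alone gained periportal -0.51, macrophage -0.30 and male-biased -1.49 and lost p53 0.74 and acinar 1.34. Centring on housekeeping genes gained cholesterol -0.24, periportal -0.32, cholangiocyte 0.26, macrophage -0.10, acute phase -0.10, male-biased -1.43 and female-biased -1.04. It lost acinar 1.55 and reversed neuroendocrine 0.080, lymphocyte 0.011, erythroid 0.15 and Rbl1 0.014. Centring on the 75th percentile lost secreted -0.42, gluconeogenesis -0.86, bile acid -1.37, Wnt -0.41, endothelial -0.46 and stellate -1.03. It gained interferon 0.021 and glycolysis, whose median was reversed (-0.11), and reversed Notch -0.087, imprinted -0.13 and cholangiocyte -0.11. All genes had a median of -0.26 in this setting, so the glycolysis list lay above them. Cyclic loess gained periportal -0.59, macrophage -0.28, male-biased -1.54 and female-biased -1.31 and reversed erythroid 0.052. Quantile normalization lost secreted -0.23 and reversed Notch -0.047 and erythroid 0.0085. Array weights gained periportal -0.60 and female-biased -1.45. Xist as a covariate lost acinar 1.10 and gained male-biased -1.84. Without the 3 arrays with low Xist there were 2806 higher and 2274 lower genes. Gluconeogenesis -0.55 and Wnt -0.30 were lost, cholesterol -0.84, glycolysis 0.28, interferon 0.35 and female-biased -1.55 gained, and imprinted -0.083 and acinar -0.12 reversed. Leaving out each array in turn gave 2348 to 3251 higher and 2284 to 3110 lower genes. The list medians that changed a call or a sign then ranged over -0.30 to -0.17 for secreted, -0.83 to -0.52 for gluconeogenesis, -0.012 to 0.16 for glycolysis, -0.037 to 0.26 for hepatocyte factors, -0.046 to 0.064 for imprinted, -0.27 to -0.21 for Wnt, -0.64 to -0.36 for periportal. They ranged over 0.042 to 0.10 for cholangiocyte, -0.43 to -0.13 for macrophage, -0.40 to -0.16 for endothelial, -0.11 to 1.81 for acinar genes (gene list: pancreatic acinar genes; lowest without tumour 1), 0.0054 to 0.30 for interferon, -1.98 to -0.29 for male-biased and -1.92 to -1.00 for female-biased genes, and -0.42 to 0.12 for Rbl1. Signal near background limits the size of the differences of Asb4, Insm1, Hey2, Cdkn2a, Esco2 and Sult3a1, signal near the top of the scale limits those of Ahsg and Alb, and no change was detectable at this level for Rbl1, the second Rb1 probe set and the second Cdk2 probe set.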

Other observations

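The tests of chromosomes, of 2 parts of each chromosome, of runs of neighbouring genes and of zonation were chosen after the values had been seen. Genes of some chromosomes shifted together. Over 11531 genes above the median level, with each array set to its own median and to the mean liver, chromosome 13 had a median of -0.51 in tumour 1, -0.38 in tumour 3, -0.56 in tumour 4 and -0.34 in tumour 5 but -0.04 in tumour 2, and 82.3% and 82.1% of its 430 genes were lower in tumours 1 and 4. Chromosome 15 had medians of 0.16, 0.22, 0.48, 0.40 and 0.43 in tumours 1 to 5 over 490 genes, and chromosome 16 of 0.32, 0.03, 0.33, 0.50 and 0.27 over 388. Other shifts beyond 0.30 were chromosome 17 in tumour 1 (0.34), chromosome 10 in tumour 4 (0.37), chromosome 18 in tumour 4 (0.34) and chromosome 4 in tumour 4 (-0.33), while the largest shift in any liver was 0.03. Chromosome membership and gene order were taken from the GRCm38.p6 assembly.

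Shorter runs of neighbours stood out as well, and the genes named here were chosen after their values were seen. In tumour 2, a run of 45 neighbouring genes on chromosome 3 from Pogz to Sf3b4, with Vps72, Scnm1 and Lysmd1, had 38 higher than in the other 4 tumours, 27 of them by 2-fold or more, and a median difference of 1.91. In tumour 3, a run of 53 genes on chromosome 16 with Cbr3, Cbr1 and Il10rb had 44 higher, 31 by 2-fold or more, and a median of 1.34. A run of 21 genes on chromosome 19 in tumour 3, with a median of -0.18, spans the Cyp2c cluster, whose members are liver genes of similar sequence. The same search found 0 runs in livers.

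A hypothesis is that these shifts follow changes of DNA copy number in the tumours. By a rotation test along the genome 5 of 95 pairs of a tumour and an autosome passed (adjusted p = 0.0019, each at the smallest p that 10000 rotations can give), chromosome 13 in tumours 1 and 4 and chromosome 15 in tumours 2, 3 and 5, and the other shifts given here did not. Each array had been set to its own median, and the mean of the 5 tumours had been taken from each gene. Differences between tumours in the first and the second part of each chromosome were then correlated. The correlation was 0.941 in tumours (rotation p = 0.0001, the smallest possible, with a median of rotated values of 0.522) and -0.212 in livers. A constant offset of a whole array and an effect of gene content equal in all tumours had been taken out, so neither gives this correlation. An effect of gene content that differs in strength between tumours was not tested. Of 15 pairs whose first part was shifted by 0.3 or more, 93.3% had the second part shifted the same way by 0.15 or more. Copy number changes of whole chromosomes may give this. For this share the mean of the tumours was not taken out and no rotation was run. A shared effect of gene content may give such shifts too where all 5 tumours had the same sign. That held for chromosomes 4, 6, 9, 11, 13, 15, 16, 17, 18 and 19. All 15 pairs lay on chromosomes of this kind, so their share cannot tell a shared effect from copy number. In tumour 2, however, the median was only -0.04 on chromosome 13 and 0.03 on chromosome 16. DNA was not analysed here. An effect of gene content equal in all tumours cannot account for the differences between tumours, and otherwise both explanations stay open.

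The pericentral and periportal lists were also set against each other in each array. The mean of 26 pericentral genes minus the mean of 27 periportal genes was -2.99 ± 0.43 (SD, n = 5) in tumours and -0.80 ± 0.09 (SD, n = 4) in livers, a difference of -2.19 with all tumours below all livers (exact permutation test, two-sided p = 0.00794, the smallest this design allows). The medians of both lists were known when this comparison was made, so it gives the size of a difference already seen and is no separate evidence of it.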
